A study of Drosophila melanogaster with 12 samples.

How the data were processed

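Gene expression was measured in fat bodies of adult Drosophila, 20 fat bodies per sample, 18 h after the start of oral P. entomophila infection or 5% sucrose feeding. There were 3 replicates each of the genotypes lpp and lpp-rgn-rnai, 12 libraries in all, sequenced on an Illumina NovaSeq instrument. The labels give neither the sex of the flies nor the full genotype of the control. No sucrose content is recorded for the infected groups, so a difference in feeding cannot be told apart from infection. The label rgn was read as regucalcin, which the series title spells Recucalcin.

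The count table holds raw counts per gene, made by the authors from trimmed reads aligned to build dm6. The labels name different tools for it. The series design text names Skewer 0.2.2, STAR 2.7.4, StringTie 2.1.2 and DESeq2 1.20, while the processing notes per the labels name Trim Galore, STAR, featureCounts and DESeq2, so the trimmer and the counter are not settled. The FPKM values as deposited by the authors are each count divided by gene length and by a scaled library size, which was checked to be proportional to the DESeq2 size factor. The group table holds the authors' mean FPKM of the 3 libraries of each group. Library totals were 17316273 to 20302756 counts. A floor of 3 counts is 0.148 to 0.173 CPM per library, and intervals from counting error alone are too narrow, since replicates differed by more than sampling noise.

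The tables hold 17692 genes, of which 134 are unannotated loci, and 17252 were matched to a current FlyBase symbol. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 4 groups (11294 genes), library sizes were scaled with TMM factors (0.907 to 1.08), and 1 quasi-likelihood model with a mean per group was fitted to all 12 libraries. The comparisons were infection in each genotype, RNAi under each treatment, and their interaction, defined as the infection effect in rgn RNAi minus that in lpp. Adjusted p are Benjamini-Hochberg values over all tested genes from the edgeR quasi-likelihood F-test, with a threshold of 0.05 and no fold threshold. The SE of a log2 fold change is the fitted value divided by the square root of F. The median SE of the interaction was 0.20 over the 7534 genes with a mean of at least 5 CPM.

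Gene lists (36) were fixed before any value was seen. The 35 lists with at least 3 tested members were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 175 tests. Members were also adjusted over their list alone. In each of the first 4 comparisons up to 10 called genes per direction with the largest fold change could be named, if their mean was at least 5 CPM and the 3 and 3 values did not overlap. So could the 4 members of each list with the lowest p and the SMP-30 family genes. Expected overlaps are products of the 2 counts divided by the genes tested. Other splits were all 10 of the 6 libraries of a comparison, and 100 drawn relabellings of the 12 for the interaction. Tissue scores are means of log2(CPM + 0.5) over marker genes. Testis and accessory gland markers were chosen after the signal was seen, and the 20 muscle markers were fixed before. A gene was called linked to testis if its correlation with the testis score within groups was over 0.8.

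Alternatives fixed before any value was seen were RLE scaling, no expression filter beyond a total count of 1, DESeq2 1.42.0, limma-trend on log2(FPKM + 1) for genes with an FPKM of at least 1 in 3 libraries, a replicate block, a log2 threshold of 1, leaving out each library, fitting only the 6 libraries of a comparison, and camera with an estimated correlation or fry. Added later were the testis score or the muscle score as a covariate, leaving out genes linked to testis with or without keeping them in the test, and fits of the 8 libraries with testis transcripts or the 9 without accessory gland transcripts. In simulated data with 200 changed genes, edgeR found 33.9 to 46% of 2-fold and 75.4 to 84.4% of 4-fold changes in the first 4 comparisons with 0 to 4 false calls. DESeq2 made 57 to 88 false calls there. Each simulated gene varied on its own, without the testis transcripts that vary together in the real libraries. Recovery and false calls can therefore differ in these data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No sequence was available, so reads were not realigned.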

Results

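Fat bodies of adult Drosophila of the lpp and the lpp-rgn-rnai genotype (lpp and rgn RNAi below) were compared after 18 h on 5% sucrose or with oral P. entomophila, with 3 libraries in each of 4 groups. The deposited counts came to 17316273 to 20302756 per library, and 11294 of 17692 genes and unannotated loci passed the expression filter and were tested. Values are log2 fold changes ± SE, or mean CPM ± SD, with n = 3 per group. An adjusted p is from edgeR for a gene and from camera for a gene list. A gene or list is called at an adjusted p under 0.05.

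Regucalcin, a calcium-binding protein of the SMP-30 family and the gene named in the series title (FBgn0030362, dm6 chromosome X, 12012377 to 12017375), was lower in the rgn RNAi genotype and lower with infection. Its level was 282, 238 and 310 CPM in the lpp sucrose libraries, 171, 129 and 137 in infected lpp, 114, 90.5 and 112 in rgn RNAi on sucrose, and 56.2, 35.1 and 35.8 in infected rgn RNAi. The RNAi genotype had 2.62-fold less transcript on sucrose (−1.39 ± 0.20, adjusted p = 0.00867) and 3.45-fold less under infection (−1.79 ± 0.20, adjusted p = 0.00265). Infection lowered regucalcin in lpp (−0.92 ± 0.20, adjusted p = 0.0258) and in rgn RNAi (−1.32 ± 0.20, adjusted p = 0.00791). The difference between these infection effects was not called (−0.40 ± 0.28, adjusted p = 0.893). The infection call in lpp was lost when any of 6 single libraries was left out (adjusted p from 0.0551 to 0.103), and no infection call on regucalcin held with the muscle marker score as covariate (−0.26, adjusted p = 0.945 in lpp; −0.57, adjusted p = 1 in rgn RNAi). With that covariate 0 genes at all were called for infection in either genotype, since the score did not overlap between sucrose and infected libraries. Its loss is therefore not particular to regucalcin and cannot decide on this gene. The infection call in rgn RNAi was lost without rgn RNAi sucrose replicate 1 (adjusted p = 0.0569) or infected rgn RNAi replicate 3 (adjusted p = 0.0624). The RNAi call on sucrose was lost without rgn RNAi sucrose replicate 1 (adjusted p = 0.053) or 2 (adjusted p = 0.0521). In the 9 libraries without accessory gland transcripts no call on regucalcin held, at log2 fold changes close to those of all 12. These were −0.83 and −1.27 for infection in lpp and rgn RNAi (adjusted p = 0.287 and 0.104), and −1.42 and −1.87 for RNAi on sucrose and under infection (adjusted p = 0.179 and 0.0554). The fit without a filter lost the infection call in lpp (−0.90, adjusted p = 0.0711), and fits of 6 libraries lost those for infection in rgn RNAi (−1.34, adjusted p = 0.101) and RNAi under infection (−1.84, adjusted p = 0.134).

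The other SMP-30 family gene, smp-30 (FBgn0038257, dm6 chromosome 3R, 14745901 to 14751246), was also lower in the RNAi genotype. Its mean was 59.9 ± 7.1 CPM in lpp and 12.8 ± 2.2 in rgn RNAi on sucrose (−2.23 ± 0.37, adjusted p = 0.0152), and 41.4 ± 18.8 and 11.5 ± 5.03 CPM under infection (−1.85 ± 0.36, adjusted p = 0.0256). Infection effects on smp-30 were not called (−0.53, adjusted p = 0.519 in lpp; −0.15, adjusted p = 0.935 in rgn RNAi). The call on sucrose was lost without any of 5 single libraries (adjusted p from 0.0546 to 0.0858), in the 9 libraries without accessory gland transcripts (−2.12, adjusted p = 0.251) and with the muscle marker score as covariate (−2.22, adjusted p = 0.0772). The call under infection was lost without infected lpp replicate 1 (adjusted p = 0.069) or infected rgn RNAi replicate 2 (adjusted p = 0.0959) or 3 (adjusted p = 0.114). It was also lost in the fit of 6 libraries (−1.91, adjusted p = 0.255), in the 9 libraries (−2.01, adjusted p = 0.139) and with the muscle marker score (−1.84, adjusted p = 0.205). Without a transcript sequence, a match of the RNAi construct to smp-30 was not tested.

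**Figure D1:**
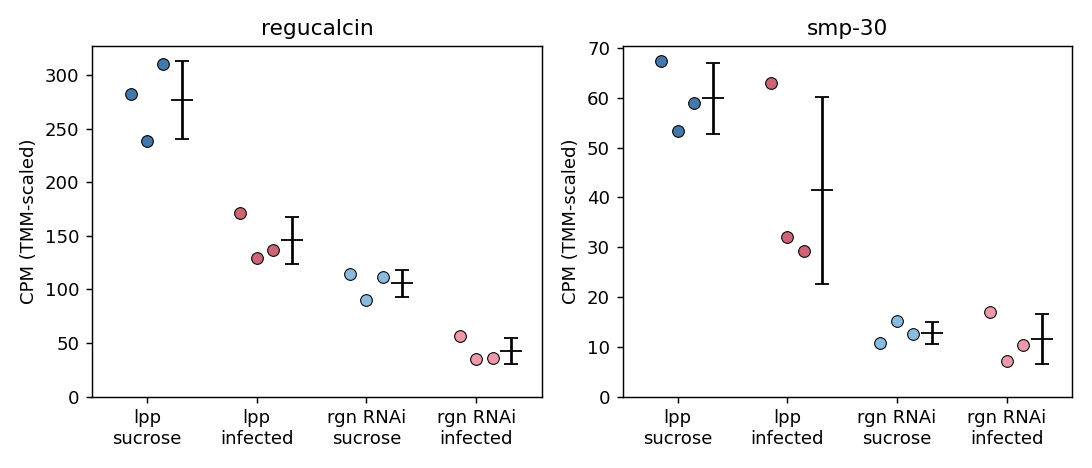
TMM-scaled CPM of regucalcin and smp-30 (y axis) in each library of the 4 groups (x axis), n = 3 per group; bars show mean and SD, 277 ± 36.2, 146 ± 22.1, 106 ± 13.1 and 42.3 ± 12 CPM for regucalcin.

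The libraries differed in transcripts of male reproductive tissue. The mean of 23 testis markers (log2 of CPM + 0.5) was 3.66 to 5.67 in 8 libraries and −0.64 to 0.20 in 4: infected lpp replicates 1 and 2, rgn RNAi sucrose replicate 1 and infected rgn RNAi replicate 1. Accessory gland markers (13 genes) were at 2.14 to 3.23 in lpp sucrose replicate 1, infected lpp replicate 2 and rgn RNAi sucrose replicate 3, and at most 0.28 elsewhere. The first principal component of log CPM over the 2000 most variable genes held 87.2% of their variance. Its absolute correlation with the testis score was 1. In all, 2567 genes tracked the testis score within groups and held 1.13 to 6.23% of the counts. They made up 11 and 0 of the genes that rose and fell with infection in lpp, 10 and 0 in rgn RNAi, 1 and 2 with RNAi on sucrose, and 4 and 1 with RNAi under infection.

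**Figure D2:**
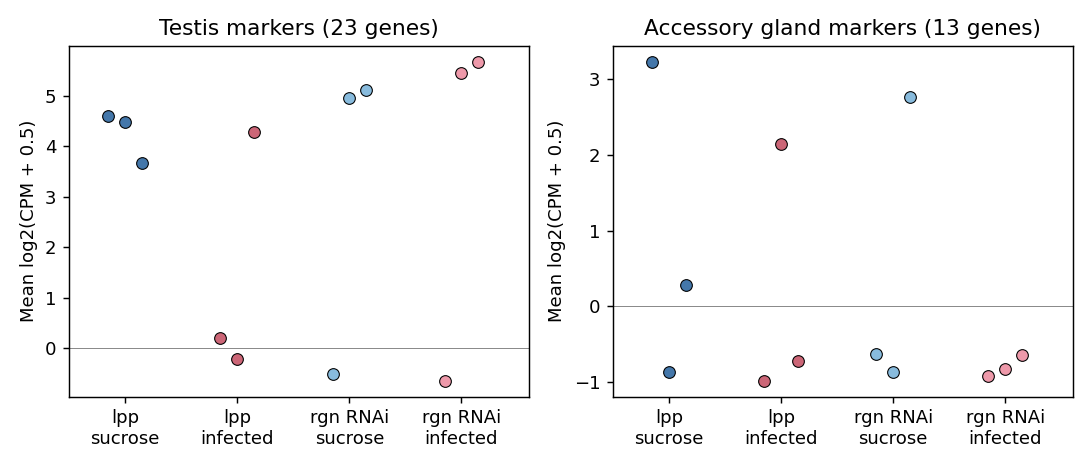
Mean log2(CPM + 0.5) of 23 testis markers (left) and 13 accessory gland markers (right) on the y axis for each library of the 4 groups on the x axis, n = 3 per group; the 8 libraries with testis transcripts lie at 3.66 to 5.67.

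In lpp fat bodies, infection raised 8 of 13 activators of the Imd pathway, which senses Gram-negative peptidoglycan. PGRP-LC, its membrane receptor, rose 4.01-fold (2.00 ± 0.13, adjusted p = 0.000131). The amidase PGRP-LB (2.83 ± 0.28), the feedback inhibitor pirk (3.02 ± 0.44) and the peptidoglycan recognition proteins PGRP-SD and PGRP-SB1 (2.20 and 4.01) rose with it. Of the activators 0 fell, and 8 rose when adjusted over the list alone. The list had a median of 0.63 (adjusted p = 1.64e-11, and adjusted p = 0.0985 with an estimated correlation). Of 9 negative regulators of Imd, 5 rose and 0 fell, also 5 when adjusted over the list alone. Its members had a median of 1.21 (adjusted p = 1.63e-05, and adjusted p = 0.285 with an estimated correlation). Toll pathway genes, among them cact (0.62 ± 0.06), the Toll inhibitor, and nec (0.66), a serpin, rose in 9 of 18 cases (10 adjusted over the list alone). The median was 0.44 (adjusted p = 1.25e-06, and adjusted p = 0.128 with an estimated correlation). Bomanins and other Toll-regulated peptides rose in 4 of 18 cases, BomS3 by 1.87 (7 adjusted over the list alone). The median was 1.31 (adjusted p = 9.24e-09, and adjusted p = 0.285 with an estimated correlation).

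The 14 antimicrobial peptides had a median of 3.49 in lpp, yet only DptB (4.61 ± 0.95, adjusted p = 0.0209) and CecC (3.33 ± 0.82, adjusted p = 0.044) passed the gene test. DptA (4.52, adjusted p = 0.0704) and Drs (2.37, adjusted p = 0.0558) did not. Adjusted over the list alone, 13 rose (list adjusted p = 3.64e-13, and adjusted p = 0.249 with an estimated correlation). The summed peptide level on sucrose was 1740 CPM in lpp replicate 1 and 250 and 186 in replicates 2 and 3. Without replicate 1, 10 peptides rose and the median was 6.01. The count of 2 was 0 without lpp sucrose replicate 2 or 3 or infected lpp replicate 2. It was 1 without infected lpp replicate 3, infected rgn RNAi replicate 2 or any rgn RNAi sucrose replicate, and 3 without infected rgn RNAi replicate 1 or 3. JAK-STAT genes rose in 5 of 12 cases, among them the cytokine upd3 (3.21 ± 0.65) (7 rose and 3 fell adjusted over the list alone). The median was 0.45 (adjusted p = 0.00559, and adjusted p = 0.376 with an estimated correlation). Melanization genes rose in 5 of 13, among them the protease Hayan (2.34) (5 rose and 1 fell adjusted over the list alone). The median was 0.37 (adjusted p = 0.00352, and adjusted p = 0.249 with an estimated correlation).

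**Figure D3:**
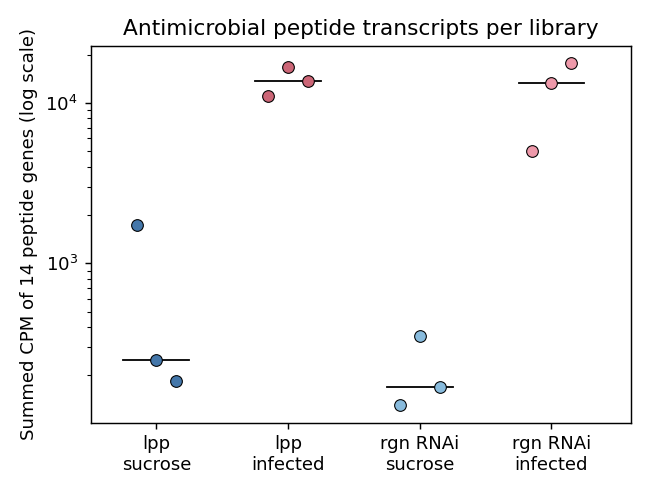
Summed CPM of 14 antimicrobial peptide genes (y axis, log scale) in each library of the 4 groups (x axis), n = 3 per group; lines mark group medians, and lpp sucrose replicate 1 lies at 1740 CPM.

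Among metabolic genes in infected lpp, the purine synthesis enzymes Gart (2.63 ± 0.20, adjusted p = 0.000357) and Pfas (1.81 ± 0.16), the sarcosine dehydrogenase Sardh (1.93) and the folate enzyme pug (1.06) were among 10 of 23 genes of folate, purine and amino acid metabolism that rose, while 1 fell (13 and 1 adjusted over the list alone). The median was 0.48 (adjusted p = 1.95e-12, and adjusted p = 0.249 with an estimated correlation). In insulin and adipokine signalling, 7 of 19 rose and 1 fell (9 and 2 adjusted over the list alone): the translational repressor Thor (1.16 ± 0.16), the insulin-binding ImpL2 (1.02 ± 0.14) and the kinase subunit Pi3K92E (0.57 ± 0.05) rose. The list had a median of 0.31 (adjusted p = 6.85e-06, and adjusted p = 0.322 with an estimated correlation). The lipase bmm (1.14 ± 0.15) and the lipoprotein receptor LpR2 (1.34 ± 0.16) rose, and mdy, a triglyceride synthesis enzyme, fell by 0.76 ± 0.08. Lipoproteins and lipid carriers rose in 3 of 10 cases (3 adjusted over the list alone). The median was 0.29 (adjusted p = 0.00148, and adjusted p = 0.249 with an estimated correlation). In trehalose and glycogen metabolism 6 of 15 fell and 2 rose, the same adjusted over the list alone. Among the 6 were the glycogen synthase Glys (−1.25 ± 0.20) and the glycogen phosphorylase Glyp (−0.96 ± 0.16). Its members had a median of −0.09 and a mean of −0.29 (adjusted p = 0.0391, and adjusted p = 0.645 with an estimated correlation). That call was lost without lpp sucrose replicate 1 or 3 (−0.11 and −0.09, adjusted p = 0.062 and 0.0541), infected lpp replicate 3 (−0.04, adjusted p = 0.193), or replicate 3 of either rgn RNAi group (−0.09 and −0.07, adjusted p = 0.063 and 0.065).

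In infected lpp, oxidative stress and glutathione genes rose in 7 of 35 cases and fell in 1 (15 and 5 adjusted over the list alone), GstD5 by 4.38 and GstD1 by 1.30. The list had a median of 0.29 (adjusted p = 5.44e-06, and adjusted p = 0.249 with an estimated correlation). Of 69 cytochrome P450s, 13 rose, Cyp309a1 by 2.93 ± 0.18, and 4 fell (22 and 8 adjusted over the list alone). The median was 0.13 (adjusted p = 0.000224, and adjusted p = 0.556 with an estimated correlation). The iron carrier Tsf1 (1.56 ± 0.22) and the ferritin subunit Fer1HCH (0.80 ± 0.07) were among 4 of 11 fat body secreted proteins that rose (4 adjusted over the list alone). The median was 0.82 (adjusted p = 1.27e-06, and adjusted p = 0.0985 with an estimated correlation). Muscle markers fell in 6 of 18 cases, Mhc by 0.93 and Act57B by 1.16 (13 adjusted over the list alone). The median was −0.51 (adjusted p = 1.52e-08, and adjusted p = 0.376 with an estimated correlation). Oxidative phosphorylation genes had a median of −0.17 and 1 of 80 fell, also 1 adjusted over the list alone (adjusted p = 9.96e-06, and adjusted p = 0.491 with an estimated correlation). Hemocyte markers had a median of −0.33 and 1 of 13 fell, Pxn by 1.47 (4 adjusted over the list alone; adjusted p = 0.00942, and adjusted p = 0.635 with an estimated correlation). Without infected lpp replicate 3 the hemocyte median was −0.37 (adjusted p = 0.0735). Among called genes with a mean of at least 5 CPM, the largest falls were those of phu (−5.83) and CG8745 (−3.66), and CG9485, which encodes a glycogen debranching enzyme, fell by 2.42 ± 0.31.

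In total 534 genes rose and 181 fell with infection in lpp, 220 and 65 of them at least 2-fold. With scaling factors from genes not linked to testis the split was 486 and 281, a share of 63.4% up against 74.7%. It was 702 and 595 (54.1%) with the testis score as covariate, and 648 and 426 (60.3%) with testis-linked genes left out. The total of 715 became 390, 348 and 317 without lpp sucrose replicate 1, 2 and 3, and 410 without infected lpp replicate 2. Of 54 named gene calls 18 were lost without some single library. The total became 65 in the 9 libraries without accessory gland transcripts and 0 with the muscle marker score as covariate. That score did not overlap between sucrose (6.90 to 7.55) and infected libraries (6.31 to 6.83).

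In rgn RNAi fat bodies, infection raised 13 of 14 antimicrobial peptides, all 14 when adjusted over the list alone. CecA2 (8.11 ± 1.75), Dro (7.66), AttA (7.18), DptA (7.07 ± 1.43, adjusted p = 0.0228), Mtk (6.23) and DptB (5.93 ± 1.01, adjusted p = 0.0124) were among them. Its members had a median of 6.25 (adjusted p = 1.83e-18, and adjusted p = 0.249 with an estimated correlation). The count of 13 was 0 without rgn RNAi sucrose replicate 1, 4 without sucrose replicate 2, and 1 without sucrose replicate 3 or infected replicate 2 or 3. It was 8 without infected lpp replicate 2 or 3. Summed peptide levels were 130, 350 and 170 CPM on sucrose and 5040, 13200 and 17700 CPM with infection. The NF-kappaB factor Rel (2.19 ± 0.27), the receptor PGRP-LC (2.15 ± 0.13, adjusted p = 0.000146) and 5 other Imd activators rose, 7 of 13 in all (9 adjusted over the list alone). The median was 0.50 (adjusted p = 5.63e-11, and adjusted p = 0.0985 with an estimated correlation). PGRP-LB (3.43 ± 0.29) and pirk (3.65 ± 0.45) were among 4 of 9 negative regulators of Imd that rose (5 adjusted over the list alone). The median was 1.07 (adjusted p = 6.97e-07, and adjusted p = 0.249 with an estimated correlation). Toll genes rose in 6 of 18 cases (7 rose and 1 fell adjusted over the list alone). The median was 0.22 (adjusted p = 0.009, and adjusted p = 0.324 with an estimated correlation), but 0.17 (adjusted p = 0.0803) without rgn RNAi sucrose replicate 3 and 0.13 (adjusted p = 0.131) without infected rgn RNAi replicate 1. Bomanins and other Toll-regulated peptides rose in 4 of 18 cases (8 adjusted over the list alone). The median was 0.79 (adjusted p = 5.6e-07, and adjusted p = 0.364 with an estimated correlation). JAK-STAT genes rose in 3 of 12 (6 rose and 1 fell adjusted over the list alone). The median was 0.44 (adjusted p = 0.000654, and adjusted p = 0.324 with an estimated correlation).

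In infected rgn RNAi fat bodies, 32 of 80 oxidative phosphorylation genes fell and 0 rose, 56 when adjusted over the list alone. Among them were ND-ASHI (−0.57) of complex I, COX6B (−0.51 ± 0.07) of complex IV and ATPsynD (−0.53) of the ATP synthase. The 32 did not hold in every setting. Over all genes 4 fell in a fit of the 6 rgn RNAi libraries, and 0 in the 9 libraries without accessory gland transcripts. The list had a median of −0.37 and a mean of −0.18 (adjusted p = 2.28e-22, and adjusted p = 0.19 with an estimated correlation). The troponin C genes TpnC47D (−2.41) and TpnC25D (−2.27) fell. Muscle markers fell in 9 of 18 cases, Mlp60A by 1.55 (16 adjusted over the list alone). The median was −0.70 (adjusted p = 5.86e-16, and adjusted p = 0.249 with an estimated correlation). Of 13 glycolysis genes 1 fell, Gapdh1 by 0.65 (5 fell and 1 rose adjusted over the list alone). The median was −0.43 (adjusted p = 2e-05, and adjusted p = 0.376 with an estimated correlation). In trehalose and glycogen metabolism 5 of 15 fell, Glys by 1.27 and Tret1-1, a trehalose transporter, by 1.10 (6 fell and 2 rose adjusted over the list alone). The median was −0.30 (adjusted p = 2.17e-05, and adjusted p = 0.324 with an estimated correlation). TCA cycle genes fell in 1 of 20 cases, SdhD by 0.51 (5 adjusted over the list alone). The median was −0.21 (adjusted p = 0.00233, and adjusted p = 0.621 with an estimated correlation), but −0.19 (adjusted p = 0.0941) without rgn RNAi sucrose replicate 1 and −0.14 (adjusted p = 0.0975) without infected rgn RNAi replicate 3. Hemocyte markers fell in 2 of 13 cases, Pxn by 1.08 (7 adjusted over the list alone). The median was −0.55 (adjusted p = 2.9e-06, and adjusted p = 0.359 with an estimated correlation).

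With infection in rgn RNAi, Gart (3.66 ± 0.21, 12.6-fold) and Pfas (1.32) were among 9 of 23 folate, purine and amino acid genes that rose, with 1 that fell (12 and 1 adjusted over the list alone). The median was 0.35 (adjusted p = 4.42e-09, and adjusted p = 0.249 with an estimated correlation). Thor (0.92) and ImpL2 (0.72) were among 7 of 19 insulin and adipokine signalling genes that rose, with 2 that fell (9 and 2 adjusted over the list alone). The median was 0.22 (adjusted p = 0.000246, and adjusted p = 0.376 with an estimated correlation), and 0.21 (adjusted p = 0.0519) without infected rgn RNAi replicate 1. Ferritin subunits Fer1HCH (0.52) and Fer2LCH (0.51) were the 2 of 11 fat body secreted proteins that rose (4 adjusted over the list alone). The median was 0.53 (adjusted p = 4.75e-05, and adjusted p = 0.0985 with an estimated correlation). Oxidative stress and glutathione genes split into 5 that rose, GstD5 by 3.85, and 4 that fell, of 35 (11 and 5 adjusted over the list alone). The median was 0.15 (adjusted p = 0.0324, and adjusted p = 0.588 with an estimated correlation). It was 0.08, 0.10 and 0.12 (adjusted p = 0.188, 0.186 and 0.185) without rgn RNAi sucrose replicate 2 or 3 or infected rgn RNAi replicate 1. The lipase bmm (1.32 ± 0.15) and LpR2 (1.37) rose, and mdy fell by 0.60.

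In total 370 genes rose and 272 fell with infection in rgn RNAi, 177 and 70 of them at least 2-fold. This majority did not hold in every setting, and more genes fell than rose without infected rgn RNAi replicate 1 (431 up and 655 down) and in the 8 libraries with testis transcripts (462 and 668). With the testis score as covariate the split was 603 and 599. The total of 642 became 184, 330 and 212 without rgn RNAi sucrose replicate 1, 2 and 3, and 1086, 203 and 192 without infected rgn RNAi replicate 1, 2 and 3. Of 59 named gene calls 34 were lost without some single library. The total became 21 in the 9 libraries without accessory gland transcripts, 26 in a fit of the 6 rgn RNAi libraries alone and 0 with the muscle marker score as covariate.

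The 2 genotypes shared 286 genes that rose and 114 that fell with infection, against 17.5 and 4.36 expected from their totals, and the libraries of the 2 comparisons are not shared. A single gene was called in opposite directions: hoka (CG13704), a septate junction gene, was higher by 0.31 ± 0.07 in infected lpp (adjusted p = 0.0364) and lower in infected rgn RNAi (−0.36 ± 0.07, adjusted p = 0.0242), with group means of 30.5, 37.9, 72.3 and 56.5 CPM. Its interaction was −0.67 ± 0.10 with an adjusted p of 0.398. Over all 11294 genes the infection effects correlated at 0.18 (Pearson, jackknife SE 0.64), and at 0.58 over the 8727 genes not linked to testis. The Spearman values were 0.05 and 0.58. The mean infection effect and the mean RNAi effect correlated at −0.01 (Pearson, jackknife SE 0.72), with a Spearman value of −0.24. Over the genes not linked to testis these were 0.23 and 0.07, so the sign depended on the measure and the genes. A gene called in 1 genotype alone (314 in lpp, 241 in rgn RNAi) is not shown to differ between them.

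**Figure D4:**
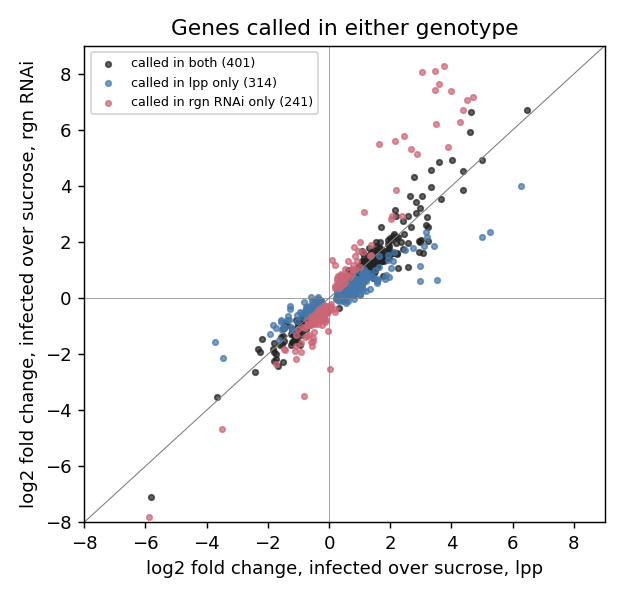
Infection log2 fold change in lpp (x axis) against rgn RNAi (y axis) for the 956 genes called in either genotype, n = 3 libraries per group; 401 genes were called in both, 314 in lpp only and 241 in rgn RNAi only, and the grey line marks equal values.

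On sucrose, transcripts of the larval storage protein Lsp1beta were 14.1-fold higher in the rgn RNAi genotype (3.82 ± 0.72, adjusted p = 0.0268). The lipophorin gene apolpp was 3.04-fold higher (1.60 ± 0.22, adjusted p = 0.00638), at 5500 ± 246 against 1810 ± 344 CPM. The lipoprotein cv-d (0.96) and the lipid droplet protein Lsd-1 (0.78) were higher as well. Lipoproteins and lipid carriers rose in 3 of 10 cases (4 rose and 1 fell adjusted over the list alone). The median was 0.11 (adjusted p = 0.00288, and adjusted p = 0.259 with an estimated correlation), but −0.02 (adjusted p = 0.053) without rgn RNAi sucrose replicate 1. Fat body secreted proteins rose in 1 of 11 (7 adjusted over the list alone). The median was 0.64 (adjusted p = 0.000556, and adjusted p = 0.0985 with an estimated correlation). The receptor tyrosine kinase Ret (4.11 ± 0.55), the chitin synthase Chs2 (2.59), CG3397 (3.77 ± 0.27), CG11378 (2.07 ± 0.12) and Hsp70Bb (4.89 ± 0.87, adjusted p = 0.022) rose. Heat shock proteins rose in 1 of 12 cases (2 adjusted over the list alone), Hsp70Bb from 0.464 ± 0.11 CPM in lpp to 13.9 ± 2.5 in rgn RNAi. Another Hsp70 gene, Hsp70Bbb, stood at 0.31 ± 0.107 and 0.58 ± 0.286 CPM, and Hsp23 at 4.84 ± 1.24 and 24.5 ± 14.9. The list had a median of 0.55 (adjusted p = 0.0204, and adjusted p = 0.588 with an estimated correlation). It was 0.24 and 0.25 (adjusted p = 0.1 and 0.0675) without lpp sucrose replicate 2 or 3, 0.29 (adjusted p = 0.0951) without rgn RNAi sucrose replicate 3 and 0.26 (adjusted p = 0.054) without infected rgn RNAi replicate 2.

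Among called genes with a mean of at least 5 CPM, the largest falls with RNAi on sucrose were in an unannotated locus on dm6 chromosome 2L (22462899 to 22463562; −6.73 ± 0.45, adjusted p = 0.000229), CG11893 (−4.46) and a second unannotated locus on 3R (4105091 to 4110236; −4.35 ± 0.38). The thioester proteins Tep1 (−1.96) and Tep4 (−0.80), the serpin Spn27A (−0.89 ± 0.10), the mitochondrial superoxide dismutase Sod2 (−0.64) and Gart (−1.23) were also lower. Of 80 oxidative phosphorylation genes 5 fell and 0 rose, 20 when adjusted over the list alone, among them COX8 (−1.23 ± 0.10, adjusted p = 0.000448), COX6B (−0.85 ± 0.07) and ATPsynB (−0.58). Its members had a median of −0.22 (adjusted p = 4.53e-18, and adjusted p = 0.249 with an estimated correlation). No muscle marker was called (0 of 18, also adjusted over the list alone), with a median of −0.22 (adjusted p = 4.33e-05, and adjusted p = 0.588 with an estimated correlation). No TCA cycle gene was called (0 of 20; 2 fell adjusted over the list alone), with a median of −0.16 (adjusted p = 0.0011, and adjusted p = 0.609 with an estimated correlation). The antimicrobial peptides had a median of −2.52 with 0 of 14 called, also adjusted over the list alone (adjusted p = 5.14e-05, and adjusted p = 0.588 with an estimated correlation). That median was −0.46 (adjusted p = 0.062) without lpp sucrose replicate 1, which held 1740 CPM, and −0.08 (adjusted p = 0.652) in the 9 libraries without accessory gland transcripts. These 9 leave out the same replicate, so the last value is not a separate result.

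In total 153 genes were higher and 118 lower with RNAi on sucrose, 55 and 35 at least 2-fold. This majority held in some fits, such as RLE scaling (142 up and 131 down) and DESeq2 (457 and 408), and not in others. The split was 169 up and 185 down with scaling factors from genes not linked to testis, 447 and 573 with the testis score as covariate, 263 and 272 with testis-linked genes left out, and 564 and 646 in the 8 libraries with testis transcripts. It was 68 and 70 without a filter, 31 and 47 without rgn RNAi sucrose replicate 1, and 88 and 95 without infected rgn RNAi replicate 3. The total of 271 became 120, 97 and 90 without lpp sucrose replicate 1, 2 and 3, and 78, 85 and 108 without rgn RNAi sucrose replicate 1, 2 and 3. Of 40 named gene calls 19 were lost without some single library. The total became 14 in the 9 libraries without accessory gland transcripts and 1020 with the testis score as covariate. Fly line and RNAi are the same samples in this design, so no value here separates them.

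Under infection, 44 of 80 oxidative phosphorylation genes were lower in the rgn RNAi genotype and 0 higher, 57 lower when adjusted over the list alone (adjusted p = 1.61e-29, and adjusted p = 0.0985 with an estimated correlation). COX8 (−1.40 ± 0.10, adjusted p = 0.000185) and COX6B (−1.27 ± 0.08, adjusted p = 0.000126) of complex IV, ND-ASHI (−0.94) of complex I and ATPsynB (−0.78) of the ATP synthase were among them. COX6B stood at 103 ± 9.37 against 247 ± 10.3 CPM. The 44 did not hold in every setting. Over all genes 7 were lower in a fit of the 6 infected libraries, and 24 in the 9 libraries without accessory gland transcripts. With the muscle marker score as covariate 4 of the 61 members not linked to testis were called lower. The list's median was −0.43 and its mean 0.05, with 18 of 19 members linked to testis positive against 1 of the other 61. TCA cycle genes fell in 4 of 20 cases, among them Mdh2 by 0.64 and Pdha, of the pyruvate dehydrogenase complex, by 0.75 (10 adjusted over the list alone). The median was −0.25 (adjusted p = 8.5e-09, and adjusted p = 0.324 with an estimated correlation). Muscle markers had a median of −0.41 with 0 of 18 called and 11 that fell adjusted over the list alone (adjusted p = 3.12e-08, and adjusted p = 0.376 with an estimated correlation). Ribosomal proteins fell in 12 of 86 cases, RpL11 by 0.58 and RpL3 by 0.47 (70 adjusted over the list alone). The median was −0.30 (adjusted p = 1.72e-28, and adjusted p = 0.324 with an estimated correlation). Over the 79 ribosomal genes not linked to testis the median was −0.32, at percentile 50.7 among random lists matched on gene length and level.

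**Figure D5:**
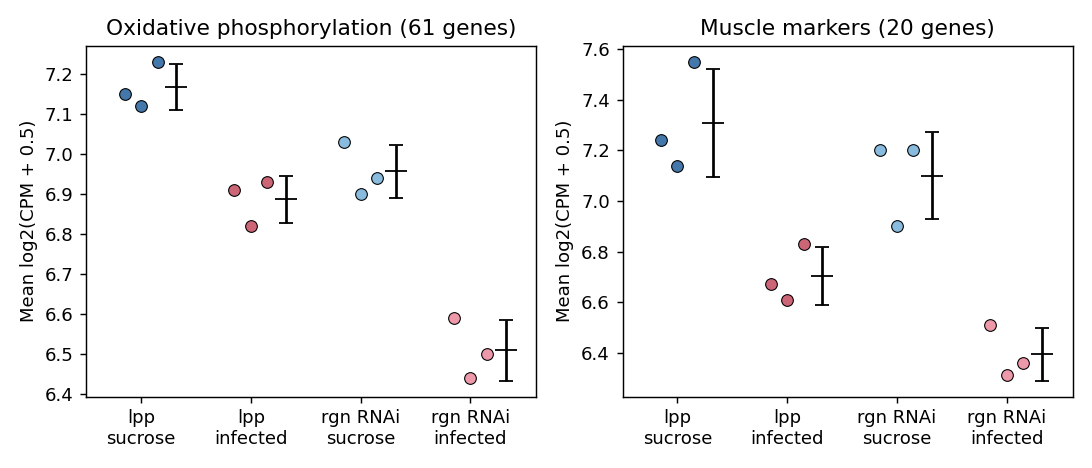
Mean log2(CPM + 0.5) of 61 oxidative phosphorylation genes not linked to testis (left) and 20 muscle markers (right) on the y axis for each library of the 4 groups on the x axis; bars show mean and SD, n = 3 per group, and the left score is 6.44 to 6.59 in infected rgn RNAi.

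With RNAi under infection, oxidative stress and glutathione genes fell in 4 of 35 cases, GstE1 by 1.07 and Sod2 by 0.89 ± 0.07 (8 adjusted over the list alone). The median was −0.24 (adjusted p = 2.95e-05, and adjusted p = 0.259 with an estimated correlation). Tep1 (−1.63), Tep4 (−1.16 ± 0.11), Spn27A (−1.08) and the Nimrod family gene NimB1 (−1.99) were lower, and 0 of 14 antimicrobial peptides were called (median −0.16). Lsp1beta (3.67 ± 0.71), apolpp (1.18 ± 0.22), Lsd-1 (0.55), Ret (4.37), Chs2 (2.92), CG3397 (2.72) and CG11378 (2.16) were higher, as on sucrose. The unannotated loci on 2L (−6.38 ± 0.43) and 3R (−5.35 ± 0.40) were lower too. Of 69 cytochrome P450s 4 rose and 10 fell, with Cyp4e3 at 2.19 and Cyp4p2 at −2.44, and that list was not called. Glycolysis genes fell in 2 of 13 cases, Eno by 0.69 (2 adjusted over the list alone). The median was −0.19 (adjusted p = 0.0152, and adjusted p = 0.637 with an estimated correlation), but −0.08 (adjusted p = 0.16) without infected lpp replicate 1 and −0.09 (adjusted p = 0.122) without infected rgn RNAi replicate 2.

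In total 133 genes were higher and 274 lower with RNAi under infection, 37 and 66 at least 2-fold. The share higher was 32.7%, against 14.7% without rgn RNAi sucrose replicate 1 and 42.6% with testis-linked genes left out. The total of 407 became 263 without lpp sucrose replicate 2, 177, 228 and 205 without infected lpp replicate 1, 2 and 3, and 893, 90 and 95 without infected rgn RNAi replicate 1, 2 and 3. Of 46 named gene calls 26 were lost without some single library. The total became 12 in a fit of the 6 infected libraries, 38 in the 9 libraries without accessory gland transcripts and 40 with the muscle marker score as covariate. The 2 RNAi comparisons, which share no library, had 78 genes higher and 94 lower in both, 0 in opposite directions, against 1.8 and 2.86 expected.

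The interaction, the difference of the infection effect between genotypes, called 0 genes with edgeR. At an unadjusted p under 0.05 it held 437 genes against 565 expected by chance, and limma called 0. DESeq2 called 31, 4 up and 27 down, among them hoka (−0.65 in DESeq2), the Nimrod genes NimB1 (−1.16) and NimB2 (−0.51) and Fer2LCH (−0.32), with edgeR adjusted p of 0.398 or more. A fit of the 8 libraries with testis transcripts, chosen after the values were seen, called CG1648 (−1.78) and Hsp70Bb (−3.47), each at an adjusted p of 0.0397. Infected lpp is 1 library there, so both calls rest on that sample, which is assumed to vary like the other groups. In simulated data with these library sizes, 18.3% of 2-fold and 57.8% of 4-fold interactions were found. Genes varied independently there, so these shares can differ in the real libraries. Among lists, camera called 16, and 0 of them with an estimated correlation. The antimicrobial peptides had a median of 2.60 (adjusted p = 0.000148, and adjusted p = 0.588 with an estimated correlation), but 0.23 (adjusted p = 0.283) without lpp sucrose replicate 1 and 0.07 (adjusted p = 0.82) without the accessory gland libraries. Those libraries include the same replicate, so the last value is not a separate result. Ribosomal proteins had a median of −0.22 (adjusted p = 4.34e-18, and adjusted p = 0.433 with an estimated correlation), and oxidative phosphorylation genes a median of −0.23 and a mean of 0.26 (adjusted p = 3.54e-08, and adjusted p = 0.364 with an estimated correlation).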

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

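The scores, covariates, matched lists and on-off gene counts in this part were chosen only after the results were seen, while the list tests and the other splits of the libraries were planned. A difference between groups marked 16 lists, all by the camera test of the interaction, and 0 of them passed with an estimated correlation (adjusted p from 0.0985 to 0.783). The list medians were 2.60 for antimicrobial peptides, −0.12 for the Toll pathway, −0.85 for Turandot peptides, −0.19 for lipid storage, −0.22 for lipoproteins and −0.25 for glycolysis. They were −0.22 for trehalose and glycogen metabolism, −0.20 for the TCA cycle, −0.23 for oxidative phosphorylation, −0.18 for oxidative stress, −0.12 for cytochrome P450s and −0.04 for autophagy. The others were −0.22 for ribosomal proteins, −0.28 for fat body secreted proteins, −2.22 for yolk proteins, with group means of 0.175 to 4.55 CPM per gene, and −0.16 for muscle. The self-contained test fry kept 2 of the 16, fat body secreted proteins (adjusted p = 0.033) and yolk proteins (adjusted p = 0.0189), and 4 remained with the testis score as covariate. The peptide difference was 0.23 (adjusted p = 0.283) without lpp sucrose replicate 1, and 9 of the 16, this list among them, were lost without some single library.

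Splits of the 6 libraries of a comparison are too few for a share under 0.05. The real split gave 715, 642 and 271 genes for infection in lpp, infection in rgn RNAi and RNAi on sucrose, where the highest other split gave 0, so 1 of 10 splits reached the real count each time. For RNAi under infection the real 407 genes stood against 2494 in another split, and 2 of 10 reached it. That other split set infected lpp replicates 1 and 2 and infected rgn RNAi replicate 1, the libraries without testis transcripts, against the rest. For the interaction the real count was 0, which any split reaches (100 of 100), so this comparison decides nothing. The highest other gave 1530.

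Testis transcripts stood at a score of 3.66 or more in 8 of 12 libraries, in 3, 1, 2 and 2 of the 3 libraries of lpp sucrose, infected lpp, rgn RNAi sucrose and infected rgn RNAi. A response of the fat body to infection or RNAi should set groups further apart than replicates, yet the largest range within a group was 6.31 against a largest difference between group means of 2.82, which argues against it as the whole source. Testis tissue left on the fat bodies stays open. The median SD of a marker around the score was 0.17 (0.086 to 0.61), but the 23 markers were chosen for this pattern and measured against their own mean, so a small SD decides nothing.

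Of the genes called in rgn RNAi under both treatments, 172 could reflect the genetic background of the line, the lower regucalcin, or both. A background difference could leave genes on in 1 line and off in the other. The rule asked for at least 10 counts in all 6 libraries of 1 line and at most 3 in each of the other 6. It was met by 0 genes, but 10 differed by more than 3 on the log2 scale under both treatments. Some of these missed the rule by few counts. The unannotated locus on 2L had 154 to 289 counts in lpp and 1 to 5 in rgn RNAi, and CG44438 had 6 to 18 and 0. The count of 0 therefore rests on the limits chosen. If the shared genes followed regucalcin, they should move the same way when infection lowers it in lpp. The signed median was 0 (quartiles −0.25 and 0.23), with 85 of 171 moving the same way. Neither test separated the explanations, since line and RNAi are the same samples.

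Oxidative phosphorylation transcripts were lower in infected rgn RNAi than in infected lpp, with a median of −0.49 over 61 members not linked to testis. With the muscle score as covariate the median was −0.37, 59 of 61 stayed negative and 4 were called against 44, so a lower share of muscle RNA could account for part and was not settled. Among 10000 random lists matched on length and level the median lay at percentile 0.01, below the lowest matched value of −0.40. The matched lists themselves had a median of −0.25, and length correlated with fold change at 0.23, so length could account for part. Random lists drew each gene independently, while members of this list can vary together. The percentile, the lowest that 10000 lists can give, therefore does not exclude length bias together with such shared variation. Each pool left out only the tested list, so ribosomal genes could enter these lists, and oxidative phosphorylation genes the ribosomal ones. No biological explanation was tested beyond the design.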

How the results depend on the processing

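The settings named for testis, accessory gland and muscle below were added only after the results were seen, and the others were planned. Totals are given for infection in lpp (715), infection in rgn RNAi (642), RNAi on sucrose (271), RNAi under infection (407) and the interaction (0). Leaving out single libraries gave 317 to 862, 184 to 1086, 78 to 400, 90 to 893 and 0 to 0 genes. Called lists, 75 of 175 tests, then numbered 66 to 84. The relation of the infection and RNAi main effects (−0.01) ranged from −0.70 to 0.16, and that of the infection effects in the 2 genotypes (0.18) from −0.14 to 0.56. RLE scaling and limma on FPKM moved no total by over 1.5 times. Without a filter, where 15525 genes entered the adjustment, 347 genes were called for infection in rgn RNAi, 138 for RNAi on sucrose and 244 for RNAi under infection. DESeq2 called 1407, 1320, 865, 1199 and 31. A log2 threshold of 1 left 285, 247, 90 and 103 by construction. Fits of 6 libraries, with fewer libraries to estimate spread, gave 473, 26, 312 and 12, so the total for RNAi on sucrose did not fall. With the testis score as covariate the counts were 1297, 1202, 1020 and 796, and without testis-linked genes 1074, 1067, 535 and 760. The 8 libraries with testis transcripts gave 1130 (infection in rgn RNAi), 1210 (RNAi on sucrose), 973 (RNAi under infection) and 2 (interaction). Infected lpp is 1 library there, so the last 2 counts rest on that sample, which is assumed to vary like the other groups. The 9 libraries without accessory gland transcripts gave 65, 21, 14 and 38. With the muscle score as covariate 0, 0, 92 (90 of them called before) and 40 were called, a score that nearly coincides with treatment. Apart from the log2 threshold, the cause of the shifts was not tested.

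The 75 lists called became 0 with an estimated correlation and 37 with fry, and 25 held in every setting but the estimated correlation. Medians that turned with the muscle covariate were 0.04 for oxidative phosphorylation and 0.11 for muscle in lpp, and 0.02 for ribosomal proteins, 0.07 for the proteasome and 0.04 for muscle in rgn RNAi. In the interaction, trehalose and glycogen metabolism turned with the testis covariate (−0.05, test direction only). The Turandot median of the interaction turned from −0.85 to 0.43 in the 8 libraries with testis transcripts. Infected lpp is 1 library there, so this turn rests on that sample. The cause was not tested. Of 199 named gene results 18 passed in every setting that was run for them, and none turned direction. Limma on FPKM ran for 197 and the fit without testis-linked genes for 192. In the first 4 comparisons 18 of 54, 34 of 59, 19 of 40 and 26 of 46 were lost without some single library. DESeq2 and RLE kept all 199, no filter 175, the 6 libraries 101, the 9 libraries 54 and the muscle covariate 48.

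With the replicate number as a block (replicate block) the counts were 892, 851, 402, 657 and 0, and 74 lists passed. Only the count for RNAi under infection moved by over 1.5 times. The block turned the majority for infection in rgn RNAi to 419 up and 432 down. Of 18 pairs with the same number 9 correlated above 0.1 (r from −0.82 to 0.95), and 6 of 12 libraries correlated best with their own number. Testis content entered these correlations. Without testis transcripts, infected lpp replicate 2 correlated with replicate 1 of rgn RNAi sucrose (0.73) and of infected rgn RNAi (0.76). The check therefore cannot decide whether equal numbers mark a shared batch. All 3 same-number pairs of rgn RNAi sucrose and infected libraries did correlate (0.95, 0.85 and 0.82), as did replicates 2 and 3 across numbers (0.83 and 0.80). Depth limits genes under the floor of 0.148 to 0.173 CPM.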

Other observations

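The artifact test, and the hypothesis it weighs, were set up only after the values were seen, while the list tests and marker lists were planned. Further lists were called by camera while few or none of their members were. Ribosomal proteins had medians of 0.16 with infection in lpp (adjusted p = 1.73e-07, and adjusted p = 0.662 with an estimated correlation), −0.07 with infection in rgn RNAi (adjusted p = 0.0223, and adjusted p = 0.839 with an estimated correlation) and −0.08 with RNAi on sucrose (adjusted p = 7.81e-05, and adjusted p = 0.783 with an estimated correlation). No ribosomal gene passed in these 3, and the last 2 list calls were lost without some single library. The proteasome had medians of −0.16, −0.20, −0.22 and −0.27 in the first 4 comparisons (adjusted p = 0.00246, 0.000425, 1.71e-07 and 4.76e-06, and adjusted p = 0.596, 0.563, 0.349 and 0.365 with an estimated correlation). The call in infected rgn RNAi was −0.11 (adjusted p = 0.05) without rgn RNAi sucrose replicate 1. Of its 48 genes 1 fell, with RNAi under infection, where the mean was 0.43 against that median. Yolk proteins, at group means of 0.175 to 4.55 CPM per gene, had a median of −1.33 with infection in rgn RNAi (adjusted p = 0.03, and adjusted p = 0.324 with an estimated correlation) and 1.43 with RNAi on sucrose (adjusted p = 0.00919, and adjusted p = 0.249 with an estimated correlation). The former was lost without rgn RNAi sucrose or infected replicate 1 (−1.18 and −1.24, adjusted p = 0.0505 and 0.105).

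Lipolysis and fatty acid oxidation genes had a median of 0.10 with infection in lpp (adjusted p = 0.0152, and adjusted p = 0.667 with an estimated correlation), and 2 of 20 rose. Malpighian tubule markers had a median of 0.55 with RNAi on sucrose (adjusted p = 0.0494, and adjusted p = 0.588 with an estimated correlation), 0 of 10 called. With RNAi under infection, Imd pathway activators had a median of −0.10 with 0 of 13 called (adjusted p = 0.0324, and adjusted p = 0.527 with an estimated correlation), and folate, purine and amino acid genes a median of −0.15 with 1 of 23 that fell (adjusted p = 0.0324, and adjusted p = 0.667 with an estimated correlation). Each of these 4 list calls was lost without some single library. The median of the folate, purine and amino acid genes turned to 0.09 (adjusted p = 0.371) without infected lpp replicate 1. The gut amylase gene Amy-p rose by 3.58 ± 0.61 with infection in lpp (adjusted p = 0.00914) and by 4.86 in rgn RNAi. Not every gut marker was higher with infection. The low level of alphaTry was 0.959 ± 0.361 CPM on sucrose and 0.0706 ± 0.0811 with infection in lpp. In rgn RNAi it was 2.79 ± 0.985 and 0.103 ± 0.135 CPM. Cyp318a1, near regucalcin on the X chromosome, was lower with RNAi on sucrose (−0.93, adjusted p = 0.0322) and under infection (−1.43, adjusted p = 0.00488). The dosage compensation RNA roX1, made in males, stood at 575 to 905 CPM in every library, and Yp1 at 2.14 CPM or less.

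Lpp sucrose replicate 1 held 1740 CPM of antimicrobial peptides against 250 and 186 in its replicates. A hypothesis was that RNA of infected flies was mixed in, or that an infected sample carried a sucrose label. If RNA was mixed in, other genes raised by infection should reach the same share of the infected level as the peptides. The peptides reached 0.19 (quartiles 0.11 and 0.26). If the label was wrong, these genes should lie near their infected level. The 111 other genes, outside the immune lists, were raised at least 2-fold with infection in rgn RNAi, and in infected lpp stood at 2 times the mean or more of lpp sucrose replicates 2 and 3. They reached a median share of 0.03, with an upper quartile of 0.091. This test excluded both forms of the hypothesis only for flies that respond like the infected libraries. Flies infected in another way or at another stage were not covered. No other explanation was tested.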
